A study of Homo sapiens with 2 samples.

How the data were processed

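RNA of the human liver cancer cell line HepG2 was measured on 1-colour Agilent microarrays after labelling with Cy3, on a design with probes for both mRNA and long noncoding RNA (lncRNA), per the labels. The shZNF717 group, in which a short hairpin RNA was directed against ZNF717, held 1 array, and the shCtrl group also held 1 array. The labels also call the control a blank control. Groups were taken from the genotype label of each sample. With 1 array per group there was no residual spread between samples, so no test was run, no p-value is given, and the differences between the arrays have no replicate check.

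Per the file headers, spot intensity was read with Agilent Feature Extraction under a 1-colour gene expression protocol, and the deposited processed signal is a linear intensity after background subtraction and spatial detrending within each array, not normalized between arrays. The software's saturation, outlier and well-above-background calls are deposited beside each spot as 0 or 1. Per the file headers both arrays shared 1 design and the same recorded scan start, so scan day did not separate the groups; whether they shared a slide was not analysed here. The processed signal of the shZNF717 array was deposited rounded to fewer digits than that of shCtrl, and only the shZNF717 header records a multiplicative detrending (root mean square 0.0470 against 0.0). The authors' deposited value table held 19081 probes, or 32.4% of the 58945 array probes, as log2 values with medians of 6.55 in shZNF717 and 6.61 in shCtrl and equal maxima of 17.16. Within each array its values ranked the probes as the scanner signal did (Spearman 1.0 and 0.999999 across probes), and they lay on average 0.061 log2 units from a quantile normalization made here. Its normalization and the rule that chose its probes are not given in the sources used here: 15790 probes well above background on both arrays were not in it, and 46 of its probes were well above background on neither.

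For the main values, the log2 of the processed signal was taken and the 75th percentile of the array probes was subtracted from each array, so a level of 0 is the 75th percentile. Spots marked as non-uniform or as population outliers on either array were left out, which took 29 spots besides control spots. With control spots included, 98 spots were marked on shZNF717 and 106 on shCtrl. The spots of a probe were averaged, which left 58952 probes. A difference is always shZNF717 minus shCtrl. Counts of at least 2-fold differences used the 33037 probes that were well above background on both arrays; no spot was saturated. For a probe well above background on only 1 array, the difference is a bound, computed against the higher of the lowest signal among probes well above background on the other array and the probe's own signal there. An SD over spots describes technical spread within 1 array per group and says nothing about spread between cultures.

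The array probes carry manufacturer IDs that are not paired with genes in the sources used here. Names were available for 20 genes whose probes, with 10 spots each, carried RefSeq accessions, all 20 of which were matched in the RefSeq gene table of assembly GRCh38.p14, and for the human GAPDH and PGK1 control probes at the 5′ and 3′ ends. The headers name hg19 for the array design, so no coordinates are given. The naming rule asked for ZNF717, the 12 largest differences in each direction at or above the median level, the 4 largest noncoding ones, up to 4 members of each described gene list with all measured members of the interleukin-6 list, and the 3 largest bounds in each direction. Only the part on list members could be applied. The remaining named genes are all those that carried an accession, a choice of probes that does not depend on their values, and 2 probe IDs per direction are given. Some of the 20 genes enter the counts but are not reported here by name. ZNF717, the lncRNA class and the list medians were therefore not analysed here. Of 41 gene lists written for liver cells, signalling and possible other cell types, 4 had a measured member and none reached the minimum of 5; no list of other cell types or of interleukin-6 signalling had a measured member.

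The named-gene rule, the gene lists, the 2-fold threshold and most alternatives were fixed before the data were examined. These alternatives were normexp background correction with an offset of 50, quantile normalization, centring on the median of probes well above background, a loess curve of the difference on the mean level (span 0.3), no filter on dim probes, a stricter one, thresholds of 1.5-fold and 4-fold, outlier spots kept, and the authors' value table. Normexp ran on the median spot signal, because the mean spot signal was not among the columns used here. Restriction to spots outside the dim regions and the use of the background-subtracted signal without detrending were chosen after seeing the data.

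Dim regions were sought by taking, in blocks of 16 rows by 12 columns of the 384 by 164 spot grid, the median difference left after the loess curve, smoothing it with a 3 by 3 median filter, and joining blocks beyond 0.4 log2 units. Shifts of repeated and control sequences inside these regions were read over all spots, because the outlier calls fall on spots that deviate from their repeats, and only for sequences well above background outside. Each named probe was set beside the 500 probes nearest to it in mean level, among array probes well above background on both arrays and outside the dim regions. For the brightest named probes, from EIF3D to RPLP1, these gave the same median of -0.97, so the match in level is loose there. The counting step was tested on simulated data for shZNF717 against shCtrl over 33037 probes, with noise drawn from the spread over repeated spots: 2 of 67 probes changed 1.5-fold were called (3.0%), 65 of 67 changed 3-fold (97.0%), 66 of 66 changed 6-fold (100.0%), and 219 of 32837 unchanged probes (0.667%). That simulation holds no spread between cultures, no dim regions and no trend with brightness. Both simulated arrays were built from the shCtrl levels. The relative noise came only from repeated probes with a shCtrl signal over 1000, with an additive term from the negative controls. Its share of unchanged probes called may therefore not hold for dim probes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.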

Results

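HepG2, an established human liver cancer cell line, was profiled after knockdown of ZNF717, a zinc-finger gene, by a short hairpin RNA (shZNF717) and as a control (shCtrl), to ask which mRNAs and lncRNAs differ in level after the knockdown. Each group held 1 array of 61184 spots and 58945 array probes. On the shZNF717 array 39169 array probes (66.5%) were well above background and the median processed signal was 31.9. On the shCtrl array 34852 (59.1%) were well above background and the median was 23.7. The 60 negative control sequences, spotted 600 times in all, had a 95th percentile of signal of 20.5 on shZNF717 and 28.1 on shCtrl, and 8.0% and 8.83% of these spots were called well above background. The number of arrays limits the precision of every difference given here, and none has a replicate check. The array probes are not paired with genes in the sources used here, so the level of ZNF717 itself was not analysed here and the group labels have no check from it.

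PGK1, the glycolytic enzyme phosphoglycerate kinase 1, was the lowest in shZNF717 relative to shCtrl among the 20 genes identified by RefSeq accession. Its log2 difference was -3.49 ± 0.12 (SD over 10 spots), an 11.25-fold lower level, with mean processed signals of 49.01 on shZNF717 and 509.5 on shCtrl. A separate control probe at the 3′ end of PGK1, much brighter, differed by -2.65 ± 0.11 (SD, 8 spots), or 6.26-fold, and the control probe at the 5′ end by -1.30 ± 0.13 (SD, 10 spots), or 2.47-fold. The 3 probes thus shared a direction on every spot but differed in size by more than the spread over spots. Of the 500 probes nearest in level, 1.4% lay below the RefSeq probe's difference, 0.4% below that of the 3′ probe and 11.8% below that of the 5′ probe. Removal of the trend with brightness by loess left differences of -3.45, -1.50 and -1.27 for the RefSeq, 3′ and 5′ probes. Under normexp on the median spot signal the RefSeq probe's difference was -2.44.

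GAPDH, glyceraldehyde-3-phosphate dehydrogenase, the other glycolytic gene with a named probe, was at -1.09 ± 0.07 (SD, 9 spots), with its 3′ control probe at -1.18 ± 0.10 (SD, 9 spots) and its 5′ control probe at -0.98 ± 0.03 (SD, 9 spots). These values lay close to the median of the 500 probes of nearest level, which was -0.97 for the RefSeq probe, and loess took the RefSeq probe to 0.10 and the control probes to -0.09 (3′) and -0.13 (5′). The 2 measured members of the 25 on the list of hypoxia and glycolysis genes, PGK1 and GAPDH, shared a direction on the main scale. After loess the GAPDH probes differed in sign, so no direction can be read for GAPDH there. After quantile normalization the RefSeq probe of GAPDH was at -0.33 and that of PGK1 at -3.44. On the main scale, which keeps the trend with brightness, the difference at the 5′ probe minus that at the 3′ probe was 0.20 for GAPDH and 1.35 for PGK1.

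Among the other genes, MTX1, a metaxin of the mitochondrial outer membrane, was at -1.20 ± 0.07 (SD, 9 spots), PRMT1, a protein arginine methyltransferase, at -1.18 ± 0.06 (SD, 8 spots) and ODC1, the first enzyme of polyamine synthesis, at -1.08 ± 0.07 (SD, 9 spots). After loess these 3 differences were -0.23, -0.20 and -0.13. The 3 measured cytosolic ribosomal protein genes of 32 on that list were RPL10 at -0.99 ± 0.33 (SD, 10 spots), RPLP1 at -0.32 ± 0.05 (SD, 9 spots) and RPS18 at -0.27 ± 0.07 (SD, 9 spots). After loess RPL10 was at -1.16 and RPLP1 and RPS18 turned to 0.98 and 1.02. After quantile normalization these 3 were at -1.17, 0.01 and 0.13, so the size of the turn depended on the method. RPL10, whose signals of 38.52 and 70.68 were far dimmer than those of the other ribosomal genes, was at -0.49 under normexp. Of the housekeeping reference genes, besides PGK1 and GAPDH, ACTB, cytoplasmic beta-actin, was at -0.21 ± 0.13 (SD, 10 spots), and loess turned it to 1.08. COX4I1, a subunit of cytochrome c oxidase and the 1 measured member of the oxidative phosphorylation list, was at -0.52 ± 0.07 (SD, 8 spots) and at 0.72 after loess. After quantile normalization ACTB was at 0.19 and COX4I1 at 0.05. None of these 4 lists reached the 5 members set as the minimum for a median.

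Smaller differences were -0.92 for PFN1, which encodes the actin-binding protein profilin 1, -0.90 for the translation initiation factor gene EIF3D and -0.81 for ARHGDIA. Others were -0.78 for the dynein light chain gene DYNLL1, -0.69 for the actin gene ACTG1, -0.68 for the histone gene H3-3A and -0.52 for RACK1, a ribosomal scaffold protein gene. Their SDs over spots were 0.02 to 0.20, and all 7 turned positive after loess (0.24 to 0.71). After quantile normalization only ARHGDIA (0.12) and RACK1 (0.05) were positive. PFN1 (-0.48), H3-3A (-0.32), ACTG1 (-0.25), DYNLL1 (-0.08) and EIF3D (-0.04) stayed negative. GRM4, a glutamate receptor gene, was well above background on 5 of its 10 spots on shZNF717 and on 9 on shCtrl, and its difference of -0.44 ± 1.35 (SD, 10 spots) was smaller than the spread over spots. Of all 20 genes, 19 were lower in shZNF717 with a median difference of -0.74 and 5 were at least 2-fold lower, while after loess 6 were lower and 14 higher and after quantile normalization 13 were lower and 7 higher. Over spots outside the dim regions described next, 5 genes were at least 2-fold lower as well, and GRM4 was at -0.0.

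**Figure D1:**
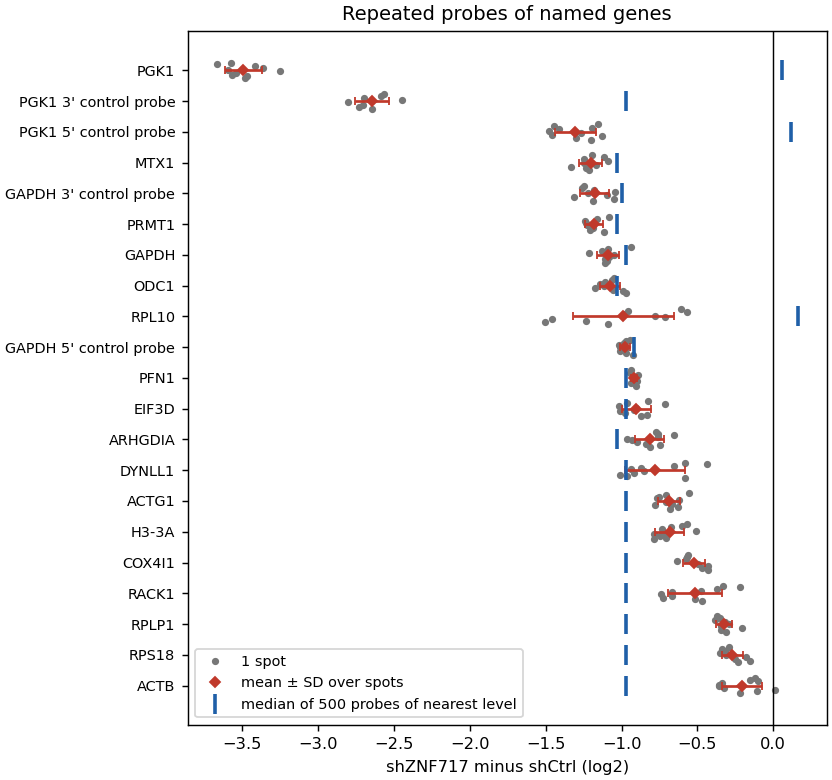
Log2 difference (shZNF717 minus shCtrl, x axis) of 17 genes named by RefSeq accession, well above background on all spots, and of the 4 human control probes for GAPDH and PGK1 (y axis). Grey points are spots, red diamonds with bars are mean ± SD over spots, and blue bars are the median of the 500 probes nearest in level. The brightest probes share a blue bar at -0.97. PGK1 lies at -3.49 while its blue bar lies at 0.06. After loess 6 of the 20 named genes are lower and after quantile normalization 13, PGK1 included each time.

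Over the 33037 probes well above background on both arrays, levels correlated at Pearson's r 0.904 and a Spearman coefficient of 0.867, across probes, which are not independent replicates. In shZNF717, 3856 probes (11.7%) were at least 2-fold higher and 5932 (18.0%) at least 2-fold lower, so that 39.4% of these differences were upward. That balance turned with the filter on dim probes: 58.5% were upward without it, and 22.7% where both arrays were at or above the median level. The median difference was -0.025 and the SD over probes 1.063. At least 4-fold differences numbered 886 higher and 1136 lower. Among probes whose mean level over both arrays was at or above the median of such means, those with the 2 largest positive differences were ASHGA5P026116, with signals of 5770 on shZNF717 and 25.8 on shCtrl, and ASHGA5P053043, with signals of 1060 and 19.8 and in the region dim on shCtrl. Both shCtrl signals lie below 28.1, the 95th percentile of the negative controls there, so the sizes are not exact. The 2 largest negative differences were those of ASHGA5P051939, with signals of 23.0 on shZNF717, close to that array's 20.5 for the negative controls, and 9674 on shCtrl, and of ASHGA5P044905, at -8.21, both outside the dim regions. Their genes are not paired with these IDs in the sources used here.

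These counts depended on where a probe lay on the slide. A region of 10298 array probes (17.5%), chiefly in rows 1 to 288 and columns 1 to 48, was dim on shCtrl, and another of 9554 probes (16.2%) in rows 241 to 384 and columns 61 to 144 was dim on shZNF717. In the region dim on shCtrl, 1737 probes (35.8%) were at least 2-fold higher in shZNF717 and 677 (13.9%) lower, with a median of 0.529. In the region dim on shZNF717, 309 (5.8%) were higher and 1716 (32.5%) lower, with a median of -0.649. Outside both, 22877 probes had a median of 0.022, and 1810 (7.9%) were at least 2-fold higher and 3534 (15.4%) lower. The regions were drawn from the differences themselves. When they were drawn from a random 50% of the array probes and read on the rest, 35.7% of the 2500 probes in the region dim on shCtrl were at least 2-fold higher and 13.6% lower (median 0.512), and 5.7% of the 2544 in the region dim on shZNF717 were higher and 33.3% lower (median -0.652). The region dim on shCtrl held 14.7% of the array probes well above background on both arrays but 45.0% of the 2-fold and 64.2% of the 4-fold higher probes.

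**Figure D2:**
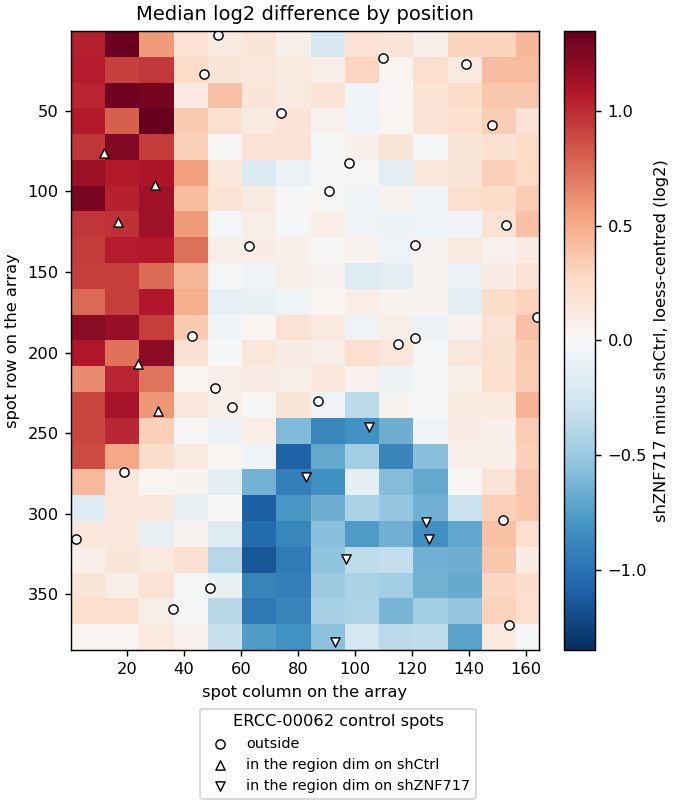
Median log2 difference (shZNF717 minus shCtrl, colour) left after the loess trend, in blocks of 16 rows by 12 columns, by spot column (x axis) and spot row (y axis). Symbols mark the spots of the control sequence ERCC-00062. The red block at the left is the region dim on shCtrl and the blue block at the lower centre the region dim on shZNF717. On the main scale, without loess, over probes well above background on both arrays, their medians were 0.529 and -0.649.

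A control sequence, ERCC-00062, was spotted in both regions and was not used to find them. Its shCtrl signal was 68.3 ± 11.6 (SD, 5 spots) inside the region dim on shCtrl and 236.6 ± 30.2 (SD, 24 spots) outside both regions, while its shZNF717 signal was 216.8 ± 8.5 and 235.0 ± 16.6 at the same spots. In the region dim on shZNF717 its shZNF717 signal was 104.8 ± 21.5 (SD, 6 spots) and its shCtrl signal 257.2 ± 18.9. The loss was not shared by all repeated or control sequences with 2 or more spots inside, read over all spots. Of those under a signal of 1000, ERCC-00062 included, 4 of 10 were lower by over 0.5 log2 units on shCtrl in its dim region and 6 stayed within 0.25, and on shZNF717 in its dim region 5 of 13 were lower by that much and 7 stayed within 0.25. The RefSeq and 5′ probes of PGK1 were among those that kept their signal on shZNF717 there, with ratios of inside to outside of 0.998 and 1.115. Of those at 1000 or more, 0 of 15 and 0 of 11 were lower by over 0.5. Without the spots in the regions, GRM4 lost its difference, from -0.44 to -0.0 over 4 spots; its SD over all spots holds the loss in the region dim on shZNF717 (ratio 0.363). None of the other 19 named genes moved by more than its SD over spots.

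Brighter probes were lower in shZNF717 than dimmer ones. Outside both regions the median difference was 0.34 in level decile 2, 0.14 in decile 5, -0.17 in decile 8 and -0.85 in decile 10, the brightest, where 76 probes were at least 2-fold higher and 968 lower. Quantile normalization and loess, which remove such a trend, gave 3879 and 3886 probes higher and 4950 and 4861 lower. Of the main 2-fold sets, 3214 of the higher and 4095 of the lower probes kept a 2-fold difference after loess, and 32 of the lower turned positive.

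**Figure D3:**
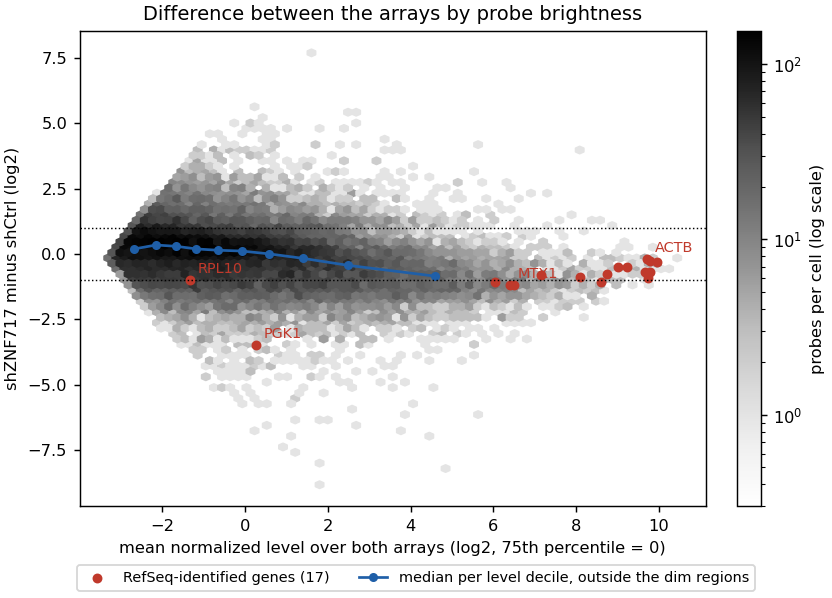
Log2 difference (shZNF717 minus shCtrl, y axis) against mean normalized log2 level over both arrays (x axis, 75th percentile at 0) for probes well above background on both arrays; grey shade is the number of probes per cell on a log scale and dotted lines mark 2-fold. The blue line is the median per level decile outside the dim regions, falling from 0.34 in decile 2 to -0.85 in decile 10. Red points are 17 genes named by RefSeq accession. PGK1 and RPL10 lie below the line, and the others lie at brighter levels than its last point.

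On shZNF717 alone 6139 probes were well above background, against 1824 on shCtrl alone. Outside the dim regions these were 3738 and 968, and in the region dim on shCtrl 1959 and 221. A bound over 1-fold was left for 5430 of the 6139 (3194 of the 3738 outside the regions) and for all 1824. The other probes seen only on shZNF717 had no higher level there than the reference taken on shCtrl. As bounds, 1598 of the probes seen only on shZNF717 were at least 2-fold higher there and 383 at least 4-fold, with a highest bound of at least 251.7-fold under the floor used. Outside the regions the bounds gave 623 and 116 probes, and the highest was at least 26.9-fold. Of the probes seen only on shCtrl, 729 were at least 2-fold and 254 at least 4-fold lower in shZNF717, with a highest bound of at least 464.3-fold, and 368 and 143 of these lay outside the regions. With the 95th percentile of the negative controls as the floor, chosen after seeing the data, the bounds were lower. They were then at least 2-fold for 353 probes and at least 4-fold for 80 on shZNF717, with a highest of 121.9-fold, and for 107 and 33 outside the regions, with a highest of 13.0-fold. On shCtrl they were so for 345 and 134, with a highest of 283.1-fold, and for 182 and 78 outside the regions.

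In the authors' deposited value table, 2464 probes were at least 2-fold higher and 3177 lower among its 19081. Its differences followed those of the scanner signal with r 0.946 across probes. The pattern by position was in it as well. Of its probes in the region dim on shCtrl 38.4% were at least 2-fold higher, in the region dim on shZNF717 32.0% were at least 2-fold lower, and outside both regions 1078 were higher and 1801 lower.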

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

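Most control probes for spike-in and rodent sequences entered no comparison of the report, and the labels do not say whether spike-in RNA was added. ERCC-00062 did enter, and most rodent probes were among the sequences counted inside the dim regions. Outside both dim regions, 3 sequences that entered no comparison were well above background on all their shZNF717 spots. They were higher there than on shCtrl by over 0.5 log2 units and over 2 standard errors over spots, which are technical repeats within 1 array per group. ERCC-00012 differed by 1.19 (22 spots), with mean signals of 37.3 on shZNF717 and 15.4 on shCtrl, where 14 of the spots were well above background. ERCC-00104 differed by 0.57 (23 spots), with signals of 31.1 and 19.8, and 20 of its shCtrl spots were well above background. Both shCtrl signals lie below 28.1, the 95th percentile of the negative controls on that array, so neither difference is an exact size. The mouse GAPDH 5′ probe differed by 0.59 (8 spots), with signals of 226.4 and 141.4. The other rodent GAPDH probes were lower on shZNF717, as the human ones were on the main scale: the rat 5′ probe differed by -0.64, the mouse 3′ probe by -0.26 and the rat 3′ probe by -0.34.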

How the results depend on the processing

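Of these settings, restriction to spots outside the dim regions and the signal without detrending were chosen after the results were seen. The 3856 higher and 5932 lower probes stayed within 1.5 times under quantile normalization, median centring, loess, outlier spots kept and signal without detrending, with 3703 to 3886 higher and 4861 to 6159 lower. The signal without detrending moved the median of all probes to 0.121, and changes there are relative to it. Normexp on the median spot signal, which changes the background correction and the signal together and adds an offset of 50, gave 1553 higher and 3673 lower. That offset lies above the median processed signals of 31.9 on shZNF717 and 23.7 on shCtrl. Added to both arrays, it shrinks the log2 differences of dim probes by construction. How much of the fall in counts came from each of these changes was not tested. Without a filter on dim probes 11938 were higher (8470 lower), as 58.5% of the differences, and with both arrays at or above the median level 1020 and 3471, as 22.7%. Thresholds of 1.5-fold and 4-fold gave 7475 and 886 higher and 9663 and 1136 lower. The value table, which holds fewer probes, gave 2464 higher and 3177 lower, with 1327 probes well above background only on shZNF717 and 477 only on shCtrl. Spots outside the dim regions, also fewer, gave 1810 higher, 3534 lower, 3738 only on shZNF717 and 968 only on shCtrl. GAPDH turned to 0.10 under loess, and it was not alone. Of the 20 named genes 19 were lower on the main scale, and 6 were lower and 14 higher after loess. The GAPDH probe is bright and loess removes the trend with brightness. Quantile normalization, which removes it as well, left GAPDH at -0.33 and 13 of the 20 lower. Among the 20 named genes quantile normalization moved 17 by more than the SD over spots, loess 16 besides GAPDH, and restriction to spots outside the dim regions 0 of 19 besides GRM4, which went from -0.44 to -0.0 while its SD held the spots left out. Normalizations do not enter the well-above-background calls and gave no other counts of them. Not run, because probe IDs were not paired with genes, were the rule for several probes of a gene and every alternative for ZNF717, lncRNA and list medians. No paired analysis was possible because each group held 1 array. Signals near the negative controls limit what can be said of dim probes such as GRM4.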

Other observations

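The tests on position and on PGK1 were chosen after those results were seen; the tests on brightness were written before theirs.

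The rodent PGK1 control probes, which enter the report only in the counts of sequences inside the dim regions, did not all follow the human ones. Outside both dim regions the mouse and rat 5′ probes differed by -1.13 ± 0.24 (SD, 8 spots) and -1.19 ± 0.18 (SD, 5 spots), the mouse 3′ probe by -0.13 ± 0.61 (SD, 6 spots) and the rat 3′ probe by 0.42 ± 0.13 (SD, 6 spots).

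The difference between the arrays depended on position on the slide. Different kinds of probes placed in different regions would shift the level on both arrays, yet the array that was not dim in a region moved by at most 0.095 log2 units there, against a shift of the difference of at least 0.506. A loss equal for all sequences is argued against by an E1A control sequence that kept at least 0.957 of its signal in both regions. A local loss, on 1 array in each region, that spares some sequences is a candidate explanation, since ERCC-00062 kept 0.446 of its signal inside the region dim on shZNF717 and 0.289 inside that dim on shCtrl, while the other array kept 1.087 and 0.923 there. What made the loss and what spares a sequence were not tested. Among probes not used to draw the regions, 35.7% were at least 2-fold higher inside that dim on shCtrl, against 7.9% outside both. In the region dim on shZNF717 33.3% of them were at least 2-fold lower, against 15.9% outside both. A response to the knockdown would not follow position on the slide, so these values argue against it as the source of either excess. Which single probes owe their difference to such a loss was not tested.

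Brighter probes were lower in shZNF717. The dim regions do not account for it, since outside both the brightest decile differed from decile 5 by -0.99, against -0.95 over all probes. An additive background error does not account for the fall between deciles 8 and 10, which both lie far above background. They differed by -0.67 after normexp and by -0.68 before, though normexp could change little at such signals. For the fall from 0.34 in decile 2 to -0.17 in decile 8, nearer to background, such an error was not tested. The bright corner control spots were at -0.74 ± 0.25 (SD, 9 spots) outside the regions, beside a median of -1.04 for the probes nearest in level. The knockdown, and other differences in labelling or scanning between the arrays, stay open and untested with 1 array per group.

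PGK1 was the lowest of the named genes. Neither the dim regions nor the trend with brightness accounts for it, since the smallest drop among its 3 probes was still -1.31 outside the regions and -1.27 after loess. Loss of RNA from the 5′ end in shZNF717 would lower the 5′ probe most. On the main scale the human 5′ probe's difference lay above that of the 3′ probe by 1.35. The 3′ probe is much brighter, and after loess the 5′ probe was at -1.27 and the 3′ probe at -1.50. Most of the gap thus went with the trend with brightness, and what is left is too small to decide on such a loss. The mouse and rat PGK1 pairs ran the other way (-1.0 and -1.61, 5′ minus 3′). The mouse and rat GAPDH pairs ran both ways (0.85 and -0.30), so the comparison speaks only of the human probes. A lower PGK1 level in the shZNF717 cells is a hypothesis found and tested on the same arrays. Whether the knockdown, the hairpin, the culture or another difference between these 2 arrays lies behind it stays open, and the rat 3′ probe went the other way.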
